A study of Homo sapiens with 6 samples.

How the data were processed

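RNA from sorted CD24-negative, CD44-positive, ESA-positive cells of MDA-MB-231, 231BoM-1833 and 231BrM-2a was hybridised to 6 Affymetrix Human Gene 1.0 ST arrays, 2 per line. The labels call the replicates biological and do not say whether they came from separate cultures or sorts, so the p-values measure the spread between these samples, which may be partly technical. The deposited values are log2 expression values, 1 per transcript cluster and array, normalised with RMA in Affymetrix Expression Console, per the submitters' processing notes and the series design text, which give no version. RMA corrects background, quantile-normalises the arrays together and summarises the probes of a cluster, so the arrays had been put on 1 scale before deposit, and a change in total RNA per cell would not show. Scanner files, detection calls, scan dates and hybridisation batches were not used here, and the labels give no batch. No background level was given with the values, so the level below which a cluster is not expressed is unknown, and folds of dim clusters are likely compressed. The tests on neighbouring genes used genes with a mean log2 value above 7, a level chosen for those tests and not a measured limit of expression.

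The value table held 33297 clusters. A platform table paired 21214 of them with at least 1 gene symbol, 19461 with exactly 1 and 1753 with several, and left 12083 unnamed here. Of 26160 symbol entries, 26098 were matched by gene number to a RefSeq gene table of assembly GRCh38.p14, and 0 needed a newer symbol. That table served for names and for which genes lie side by side; the genome build behind the array design is not given in the sources used here, and no coordinates are printed. Genes were named only from clusters with 1 symbol, which carried 18418 symbols. Where a symbol sat on more than 1 cluster (769 symbols), the cluster with the highest mean over all 6 arrays was used. Among the named calls, the clusters of a symbol had opposite signs only for PECAM1 in 231BrM-2a against MDA-MB-231 (2 clusters, -0.38 and 0.014). In 302 cases, clusters had identical values to another, 708 clusters in all, as happens with probes shared between near-identical genes or alternative versions of a region such as the HLA genes, so SPANXB1 and similar families cannot be told from their copies.

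The tests fitted a mean per line to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options), two-sided, with Benjamini-Hochberg adjustment over the 21214 named clusters and a threshold of 0.05. The 3 residual degrees of freedom were joined by 6.06 prior degrees of freedom. All 3 lines share 1 estimate of the spread, because 2 arrays per line leave too few degrees of freedom alone. For 38 gene lists, camera compared the genes of a list with all other genes, using 1 cluster per symbol and a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. Camera with a correlation estimated per list and fry were the alternatives. Camera's estimated form uses only the residual degrees of freedom here. The estimates ran from -0.22 for the genes reported low in brain-seeking derivatives to 0.84 for proliferation. They were 0.48 for NF-kappaB targets, 0.3 for class II genes and 0.15 for interferon-stimulated genes. Where an estimate exceeds the preset 0.01, the preset p may be too small. Fry's directional p asks whether a list's genes move, on balance, 1 way, without comparing them with other genes. Fry's mixed p, which asks for change in either direction, was under 0.05 for 37, 38 and 37 of the 38 lists in the comparisons of bone line with parental, brain line with parental and brain line with bone line. The median, mean and test of a list had the same sign for every list that camera called, and differed for 10, 5 and 4 of those it did not call. The lists it did not call had a camera adjusted p of 0.0553 to 0.982, 0.0631 to 0.863 and 0.0805 to 0.959.

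The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except a block with crossed replicate numbers and all tests of explanations in the closing section, which were devised once the patterns had been seen. The rule took the 12 highest and 12 lowest log2 changes of each derivative against MDA-MB-231 among clusters with 1 symbol, an adjusted p under the threshold and groups that did not overlap, and the 8 highest and 8 lowest between the derivatives. Groups of 2 arrays often fail to overlap by chance, so that condition adds little. It also took up to 4 members of each list with the largest change past the threshold, or the largest change as a value where none passed, the sort markers, 10 genes known from work on these lines (HAS2, KLF4, CXCR4, IL11, CCN2, SPP1, MMP1, PTGS2, HBEGF and ST6GALNAC5), and for the overlap the 8 highest and 8 lowest by the smaller change. Uncharacterised loci, small RNAs and antigen receptor segments were passed over. KLF4 was not called in any comparison (adjusted p 0.757, 0.899 and 0.874). CIITA was taken in 231BrM-2a against MDA-MB-231 by the rule, and its value in the bone line, like the medians over genes beside the class II genes, was added after the class II result was seen.

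The alternatives were the replicate number as a block, quantile normalisation of the deposited values, arrays centred on their medians, the dimmest 33.3% of clusters left out, all clusters with or without a symbol, 1 cluster per symbol, an intensity trend, robust eBayes, only the 2 groups compared, a change of at least 2-fold, and each array left out in turn. The lists were run again with camera's estimated correlation, fry, the block, quantile normalisation, the dimmest clusters left out, the trend and each array left out. A line left with 1 array was taken to vary like the others. The scripts were tested on simulated data for the comparison of 231BoM-1833 with MDA-MB-231. Of 50 clusters changed by each fold, 36 were recovered at 1.5-fold and 50 each at 2-fold, 4-fold and 8-fold, and 18 of the unchanged clusters among 21214 were called. A list of genes shifted by 0.5 was called and 0 of the 37 others were (18418 genes). The simulated genes varied independently, so this does not test the list calls where the genes of a list correlate. Groups of 2 allow no test for an outlying array and no count over other splits of the samples. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.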

Results

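Transcript levels were measured on 6 arrays in sorted cells of 3 related human breast cancer lines, with 2 biological replicates of each. MDA-MB-231 is a widely used line of mesenchymal, triple-negative character. 231BoM-1833 and 231BrM-2a are derivatives of it that were selected for metastasis to bone and to brain. In each line, magnetic sorting kept cells that lacked CD24 and carried CD44 and ESA, the protein encoded by EPCAM, a surface profile used to enrich cancer stem cells. The question put to the arrays was how the sorted cells of each metastatic line differ from those of the parental line. The 2 derivatives were also compared with each other. The median log2 value per array lay between 6.58 and 6.64. Across the 21214 clusters with a gene symbol, replicate arrays correlated at r = 0.9935 to 0.9959 (3 pairs) and arrays of different lines at r = 0.9666 to 0.9832 (12 pairs). These correlations run across transcript clusters, which are not independent replicates. The small number of arrays limits the precision of every value below. Group values are given as log2 mean ± SD (n = 2), differences as log2 change ± SE or as fold, and p-values come from limma with Benjamini-Hochberg adjustment unless camera is named.

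The 3 markers used for the sort are reported here as a check of level only, since the cells were chosen by them. CD44 was high in all lines, at 11.86 ± 0.0075 in MDA-MB-231 and 11.45 ± 0.0077 in 231BrM-2a, with 231BoM-1833 at 0.14 ± 0.13 above MDA-MB-231. CD24 stood at 6.12 ± 0.11 in MDA-MB-231, 6.12 ± 0.52 in 231BoM-1833 and 5.91 on both arrays of 231BrM-2a. EPCAM stood at 8.03 ± 0.14, 7.80 ± 0.73 and 8.19 ± 0.061 in the same order. The adjusted p of these markers was between 0.055 and 0.993 in the comparisons with the parental line. Between the derivatives, CD44 was lower in 231BrM-2a by 0.54 ± 0.13 (adjusted p = 0.014), a call lost without 231BoM-1833 replicate 1 (0.0565), 231BrM-2a replicate 1 (0.074) or 231BrM-2a replicate 2 (0.0704). CD24 and EPCAM did not pass there (adjusted p = 0.515 and 0.351).

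In the sorted cells of the bone-selected line, IL13RA2, a decoy receptor for an interleukin, rose the most, from 5.43 ± 0.23 in MDA-MB-231 to 9.61 ± 0.069 in 231BoM-1833, which is 18.2-fold (4.19 ± 0.14, adjusted p = 2.4e-06). CXCR4, the chemokine receptor that bone marrow stroma engages through its ligand, rose from 6.78 ± 0.038 to 9.59 ± 0.053 (2.81 ± 0.15, adjusted p = 1.19e-05). The pro-inflammatory cytokine gene IL1B rose 6.89-fold, to 12.03 ± 0.36, and IL24 rose 8.66-fold (adjusted p = 9.26e-05 and 0.000156). TNFSF18, a ligand of the tumour necrosis factor family, fell the most, from 9.24 ± 0.29 to 5.49 ± 0.59, a 13.5-fold difference (adjusted p = 0.00321).

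Other genes with large increases in 231BoM-1833 were F2RL2, a protease-activated receptor (14.0-fold), CYP24A1, the enzyme that inactivates vitamin D hormone (11.5-fold), the membrane mucin gene MUC15 (9.76-fold) and SPARC, a matricellular glycoprotein (9.25-fold). Their adjusted p lay between 2.4e-06 and 0.000138. The unconventional myosin gene MYO1D rose 7.59-fold. Among the genes that fell were MAOA, which encodes a monoamine oxidase (4.76-fold, adjusted p = 0.000142), IL7R, an interleukin receptor chain (4.28-fold, adjusted p = 0.000377), and HSD17B2, which oxidises estradiol (4.28-fold, adjusted p = 6.63e-05). ZBTB16, a transcriptional repressor, fell 4.03-fold, and ITGA10, a collagen-binding integrin chain, fell 3.89-fold (adjusted p = 0.00011 and 0.000122).

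Genes of MHC class II antigen presentation rose together in 231BoM-1833. Of 10 measured genes, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 7.32e-07, adjusted p = 0.473 with an estimated correlation). HLA-DPA1 rose 5.21-fold, HLA-DMB 4.11-fold, HLA-DPB1 3.78-fold and HLA-DMA 3.63-fold. CIITA, the transcriptional activator of class II genes, had a difference of 0.054 ± 0.13 (adjusted p = 0.805). Of 15 leukocyte markers, 1 rose, CD14, and 1 fell (camera adjusted p = 0.886). Of 11 red cell, platelet and endothelial markers, 1 rose and 1 fell (camera adjusted p = 0.871). Class I presentation genes also rose, 5 up and 1 down of 10, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00373, adjusted p = 0.473 with an estimated correlation). They included the immunoproteasome genes PSMB8 (2.22-fold) and PSMB9 (2.04-fold).

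Interferon-stimulated genes rose in 231BoM-1833 as well, 14 up and 0 down of 34 measured. Adjusted over the list alone, 17 rose and 2 fell (camera adjusted p = 1.27e-05, adjusted p = 0.54 with an estimated correlation). BST2, which tethers enveloped viruses to the cell, rose 3.59-fold, IFI6 2.59-fold and IFI27 2.37-fold. Among cytokines and chemokines, 9 of 25 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 3.36e-05, adjusted p = 0.473 with an estimated correlation). IL1A rose 4.38-fold beside IL1B and IL24. Of 21 NF-kappaB target genes, 7 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000993, adjusted p = 0.739 with an estimated correlation). That list was no longer called without 231BoM-1833 replicate 1 (camera adjusted p = 0.178) or with fry (adjusted p = 0.29). Immediate early and dissociation genes, which also answer to cell handling, moved the same way. Of 20, 5 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00373, adjusted p = 0.594 with an estimated correlation). JUN, a subunit of the AP-1 transcription factor, rose by 1.14 ± 0.11. Fry did not call this list (adjusted p = 0.113).

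Matrix proteases and their inhibitors rose, 11 up and 1 down of 25, or 13 and 1 adjusted over the list alone (camera adjusted p = 9.8e-05, adjusted p = 0.473 with an estimated correlation). PLAU, the urokinase gene, rose 2.34-fold, its receptor gene PLAUR 2.42-fold and the cathepsin gene CTSS 3.56-fold. The inhibitor gene TIMP3 rose 2.16-fold. The collagenase gene MMP1 had a difference of 1.17 ± 0.39 (adjusted p = 0.0729), from an already high 12.69 ± 0.078.

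Lists of metastasis genes were taken from earlier work on lines of this same family, so their direction here is not independent evidence. Of 10 genes reported high in bone-seeking derivatives, 4 rose and 0 fell in 231BoM-1833, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.000604, adjusted p = 0.473 with an estimated correlation). CXCR4 and the growth factor gene FGF5 (4.18-fold, adjusted p = 0.0012) had the largest changes. CCN2 rose 1.61-fold, but was not called without MDA-MB-231 replicate 2 (adjusted p = 0.0908), and ADAMTS1 rose 1.63-fold, but was not called without MDA-MB-231 replicate 1 (adjusted p = 0.0522). IL11 (0.13 ± 0.16, adjusted p = 0.607) and SPP1 (-0.15 ± 0.11, adjusted p = 0.389) did not pass the test. Of 16 genes reported high in lung-seeking derivatives, 7 rose and 5 fell, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.0188, adjusted p = 0.594 with an estimated correlation). IL13RA2, SPARC, TNC (4.74-fold) and PTGS2 (4.58-fold) were the risers with the largest changes. The 14 genes reported high in brain-seeking derivatives were not called as a list, with 5 up and 3 down, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.566).

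Lists for the unfolded protein and amino acid responses and for heat shock were also called in 231BoM-1833. In the former, 6 of 26 rose and 0 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.722 with an estimated correlation). The stress-induced transcription factor gene DDIT3 rose 4.74-fold (adjusted p = 0.00257). The list was not called without 231BoM-1833 replicate 2 (camera adjusted p = 0.0784) or with fry (adjusted p = 0.29). In the heat shock and oxidative stress list, 4 of 21 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0438, adjusted p = 0.685 with an estimated correlation). It was not called without MDA-MB-231 replicate 1, MDA-MB-231 replicate 2 or 231BoM-1833 replicate 1 (camera adjusted p = 0.0511, 0.0822 and 0.377), nor after quantile normalization (0.111), with the dimmest 33.3% of clusters left out (0.0925) or with fry (0.215).

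In all, limma called 3354 of 21214 clusters between 231BoM-1833 and MDA-MB-231, 1789 higher and 1565 lower in the bone-selected line (1725 and 1736 with the dimmest 33.3% of clusters left out). Of the 393 that differed at least 2-fold, 335 were higher and 58 lower. Camera called 11 of 38 lists, all higher. Collagens went the other way, 1 up and 5 down of 19, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.0553, adjusted p = 0.54 with an estimated correlation). They were called lower with fry (adjusted p = 0.0167), with the dimmest 33.3% of clusters left out (camera adjusted p = 0.023) and without MDA-MB-231 replicate 2 (0.0424) or 231BoM-1833 replicate 2 (0.0226). With an estimated correlation, which rests on the 3 residual degrees of freedom, camera called 0 lists, while 3 had an unadjusted p under 0.05 and fry called 8. The cluster count fell when either MDA-MB-231 array was left out. It was 2220 when clusters with no symbol were tested too, but 590 of these had no symbol. Of the 3354 calls, that setting kept 1630 (48.6%).

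**Figure D1:**
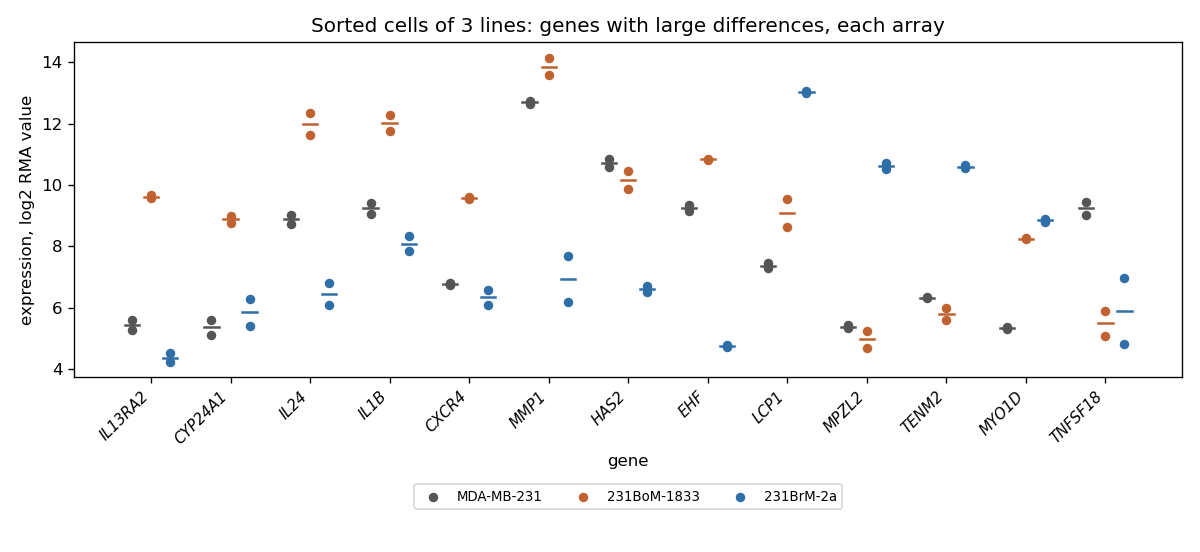
Expression (log2 RMA value, vertical axis) of 13 genes on each of the 6 arrays, with a dot per array and a bar at the mean of the 2 arrays of a line. IL13RA2, IL24, IL1B and CXCR4 sit highest in 231BoM-1833, LCP1, MPZL2 and TENM2 sit highest in 231BrM-2a, and MMP1, HAS2 and EHF sit lowest there, MMP1 at 6.93 against 12.69 in MDA-MB-231.

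In the sorted cells of the brain-selected line, LCP1, MPZL2 and TENM2 rose the most and MMP1 fell the most. LCP1, an actin-bundling protein gene usually tied to blood cells, rose 50.2-fold, from 7.38 ± 0.13 in MDA-MB-231 to 13.03 ± 0.056 in 231BrM-2a (5.65 ± 0.24, adjusted p = 2.97e-06). MPZL2, an epithelial adhesion protein gene, rose 37.8-fold, and TENM2, a teneurin with a role in neuronal contacts, rose 19.3-fold (both adjusted p = 5.33e-07). MMP1 fell from 12.69 ± 0.078 to 6.93 ± 1.1, a 54.4-fold difference (-5.77 ± 0.39, adjusted p = 3.13e-05), which was 91.1-fold without 231BrM-2a replicate 1 and 32.4-fold without replicate 2. HAS2, which encodes a hyaluronan synthase, fell 17.3-fold, from 10.72 ± 0.18 to 6.61 ± 0.14 (-4.11 ± 0.19, adjusted p = 3.98e-06).

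The long non-coding RNA UCA1 rose 18.6-fold in 231BrM-2a, and CRISPLD2, a secreted protein gene, rose 14.7-fold. MYO1D rose 11.5-fold, the smooth muscle actin-binding protein gene TAGLN 10.2-fold and the protease inhibitor gene SLPI 7.79-fold. The adjusted p of these 5 lay between 4.51e-07 and 2.87e-05. EHF, an epithelial transcription factor gene, fell 22.9-fold (adjusted p = 2.84e-07). CHRDL1, an antagonist of bone morphogenetic proteins, fell 14.0-fold, SEMA3A, a guidance cue, 9.04-fold, and the innate immune receptor gene TLR2 8.28-fold (adjusted p = 4.51e-07, 1.32e-06 and 7.05e-05).

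Interferon-stimulated genes were the list with the lowest camera p at the preset correlation in 231BrM-2a against MDA-MB-231. Of 34 measured, 26 rose and 0 fell, or 28 and 0 adjusted over the list alone (camera adjusted p = 8.75e-21, adjusted p = 0.362 with an estimated correlation). IFIT1, which binds foreign RNA, rose 8.17-fold (3.03 ± 0.15, adjusted p = 6.18e-06), XAF1 4.66-fold, MX1, an antiviral GTPase gene, 4.37-fold and EPSTI1 3.62-fold. Class I presentation genes were called higher, 5 up and 1 down of 10 with the same counts adjusted over the list alone (camera adjusted p = 0.0394, adjusted p = 0.476 with an estimated correlation). That call was lost without MDA-MB-231 replicate 2 (camera adjusted p = 0.0996), without 231BrM-2a replicate 1 (0.0795) and with the dimmest 33.3% of clusters left out (0.12). The light chain gene B2M rose 1.74-fold (adjusted p = 0.0024). The class II list was not called, with 1 up and 2 down of 10 and the same counts adjusted over the list alone (camera adjusted p = 0.456). CIITA had a difference of -0.45 (adjusted p = 0.0369), a call lost when clusters with no symbol were tested too (0.0937). Of 15 leukocyte markers, 0 rose and 2 fell (camera adjusted p = 0.336), and of 11 red cell, platelet and endothelial markers, 0 rose and 3 fell (camera adjusted p = 0.281), a list that fry called lower (adjusted p = 0.0283).

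TGF-beta and YAP target genes rose in 231BrM-2a, 10 up and 1 down of 20, or 11 and 2 adjusted over the list alone (camera adjusted p = 5.84e-05, adjusted p = 0.467 with an estimated correlation). TGFBI, a matrix protein gene named for its induction by TGF-beta, rose 7.25-fold (adjusted p = 2.97e-06), the ligand gene TGFB2 2.92-fold and ID3, an inhibitor of helix-loop-helix factors, 2.47-fold. Of 26 hypoxia and glycolysis genes, 12 rose and 2 fell, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.000455, adjusted p = 0.557 with an estimated correlation). The glycolytic enzyme genes ALDOC (2.92-fold) and ENO2 (2.42-fold) rose, while VEGFA, an angiogenic factor gene, fell 2.41-fold. Of 34 proliferation genes, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.00424, adjusted p = 0.798 with an estimated correlation). The cyclin gene CCNB2 rose 1.91-fold. The list was not called without 231BrM-2a replicate 2 (camera adjusted p = 0.0568) or with fry (adjusted p = 0.353). In the oxidative phosphorylation list, 5 of 25 rose and 1 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0103, adjusted p = 0.724 with an estimated correlation). It was not called without MDA-MB-231 replicate 2 (0.0793), 231BrM-2a replicate 2 (0.0715), with the dimmest 33.3% of clusters left out (0.0737) or with fry (0.149).

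The genes reported earlier for brain-seeking derivatives, known from lines of this family and so not independent evidence, moved against their reported direction. Of 14 reported high, 0 rose and 8 fell, or 1 and 9 adjusted over the list alone (camera adjusted p = 0.00179, adjusted p = 0.467 with an estimated correlation). Besides MMP1, the laminin chain gene LAMA4 fell 4.14-fold (adjusted p = 8.41e-05) and LTBP1, which binds latent TGF-beta, 1.91-fold (adjusted p = 0.00181). The cyclooxygenase gene PTGS2 (-0.10 ± 0.26, adjusted p = 0.824) and the sialyltransferase gene ST6GALNAC5 (-0.39 ± 0.16, adjusted p = 0.119) did not pass the test. Of 4 reported low, 3 rose and 0 fell, the same counts as adjusted over the list alone (camera adjusted p = 5.84e-05, adjusted p = 0.362 with an estimated correlation). They were the death ligand gene TNFSF10 (6.63-fold), the sodium channel subunit gene SCNN1A (4.79-fold) and PLAAT4 (2.58-fold). The bone list was not called, with 0 up and 3 down of 10, or 0 and 5 adjusted over the list alone (camera adjusted p = 0.124), but was called lower with fry (adjusted p = 0.0389) and without 231BrM-2a replicate 2 (camera adjusted p = 0.0155). CXCR4 had a difference of -0.44 ± 0.15 (adjusted p = 0.0762).

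Cancer-testis antigen genes fell in 231BrM-2a, 7 down and 1 up of 15, with the same counts adjusted over the list alone (camera adjusted p = 0.00179, adjusted p = 0.385 with an estimated correlation). SPANXB1, which belongs to a family of near-identical copies, fell 18.9-fold (adjusted p = 1.44e-06), and SSX1 fell 3.08-fold. Of 22 HOX genes, 4 fell and 0 rose, as adjusted over the list alone (camera adjusted p = 0.0394, adjusted p = 0.557 with an estimated correlation). All 4 were HOXB genes: HOXB9 fell 2.18-fold (adjusted p = 0.000137), and the others were HOXB3, HOXB5 and HOXB6. Of the HOXA genes in the list, only HOXA2 was measured, and HOXC6 was not. The HOX call was lost without MDA-MB-231 replicate 2 (0.129), 231BrM-2a replicate 1 (0.061) or 231BrM-2a replicate 2 (0.0568), after quantile normalization (0.0722) and with the dimmest 33.3% of clusters left out (0.162). Hyaluronan genes were not called as a list, with 3 up and 1 down, HAS2, of 17 and the same counts adjusted over the list alone (camera adjusted p = 0.676).

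Between 231BrM-2a and MDA-MB-231, limma called 4040 of 21214 clusters, 2217 higher and 1823 lower in the brain-selected line, a majority that turned to 2021 higher and 2125 lower with arrays centred on their medians. Of the 625 that differed at least 2-fold, 413 were higher and 212 lower. Camera called 7 lists higher and 3 lower, against 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 14 with fry. The cluster count was 2390 without MDA-MB-231 replicate 1, 1764 without MDA-MB-231 replicate 2, 2180 without 231BrM-2a replicate 1 and 2016 without 231BrM-2a replicate 2.

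**Figure D2:**
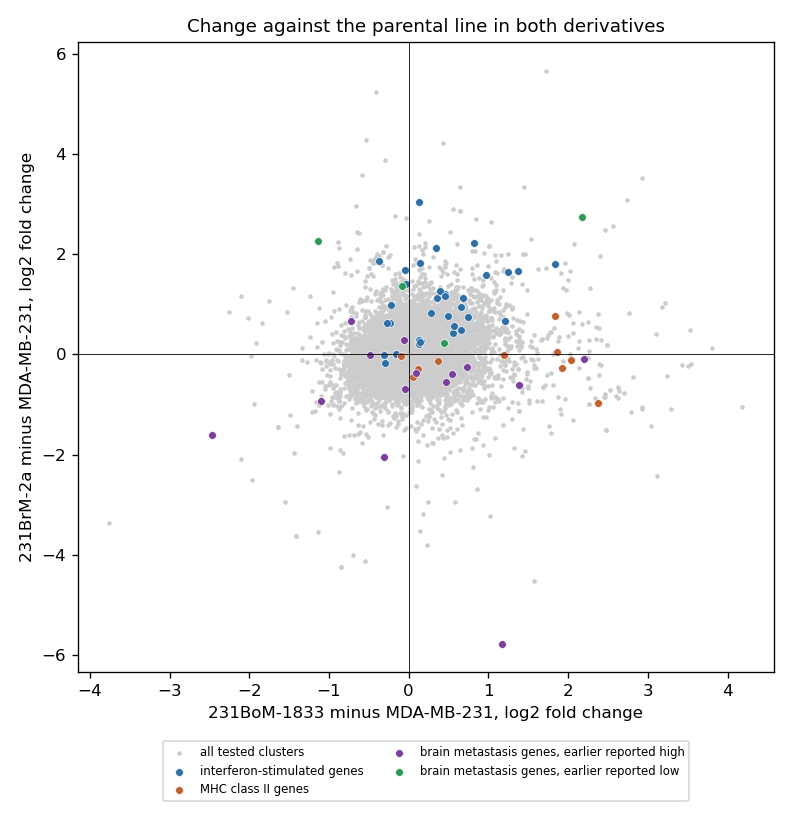
Log2 change against MDA-MB-231 in 231BoM-1833 (horizontal axis) and in 231BrM-2a (vertical axis), 1 point per tested cluster, with 4 gene lists in colour. Interferon-stimulated genes lie mostly above 0 on the vertical axis, several class II genes lie to the right at up to 2.38, and MMP1 lies alone at the bottom, at -5.77.

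Between the derivatives, MMP1 differed the most. It was 122-fold lower in 231BrM-2a than in 231BoM-1833 (-6.93 ± 0.39, adjusted p = 4.8e-06), or 205-fold without 231BrM-2a replicate 1 and 72.9-fold without replicate 2. EHF was 68.4-fold lower, IL24 46.6-fold and IL13RA2 37.6-fold (adjusted p = 1.9e-08, 1.62e-06 and 2.01e-07). IL1B was 15.4-fold lower, HAS2 11.8-fold and CXCR4 9.52-fold. Higher in 231BrM-2a were MPZL2 (by 5.64 ± 0.17), TENM2 (28.1-fold), SCNN1A (10.6-fold) and IL7R (9.55-fold), with adjusted p between 2.27e-07 and 8.87e-06.

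Class II presentation genes stood lower in 231BrM-2a than in 231BoM-1833, 9 down and 0 up of 10 with the same counts adjusted over the list alone (camera adjusted p = 4.19e-07, adjusted p = 0.407 with an estimated correlation). HLA-DPA1 was 10.1-fold lower. Of 15 leukocyte markers, 0 were higher and 2 lower (camera adjusted p = 0.242). Genes that lie beside the class II genes were lower too, with a median log2 difference of -0.639 over 25 genes with a mean log2 value above 7 on 1 side and -0.317 over 25 on the other. Bone metastasis genes were lower, 6 of 10 and 0 higher, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000107, adjusted p = 0.407 with an estimated correlation). FGF5 was 10.3-fold lower (adjusted p = 2.47e-05). Matrix proteases were lower, 14 down and 3 up of 25 with the same counts adjusted over the list alone (camera adjusted p = 0.00018, adjusted p = 0.407 with an estimated correlation). PLAT, the tissue plasminogen activator gene, was 5.73-fold lower. Cytokines and chemokines were lower, 10 down and 5 up of 25 with the same counts adjusted over the list alone (camera adjusted p = 0.00352, adjusted p = 0.514 with an estimated correlation). CXCL8, a neutrophil chemokine gene, was 5.76-fold lower (adjusted p = 0.000112).

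Interferon-stimulated genes were higher in 231BrM-2a than in 231BoM-1833, 17 up and 1 down of 34, or 19 and 1 adjusted over the list alone (camera adjusted p = 3.68e-07, adjusted p = 0.407 with an estimated correlation). IFIT1 was 7.46-fold higher and EPSTI1 4.67-fold. Collagens were higher, 10 up and 3 down of 19, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.00292, adjusted p = 0.407 with an estimated correlation). The basement membrane chain genes COL4A1 (10.43 ± 0.0052 against 7.43 ± 0.25) and COL4A2 (5.31-fold) led them. TGF-beta and YAP targets were higher, 11 up and 1 down of 20, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00131, adjusted p = 0.432 with an estimated correlation), with TGFBI at 4.62-fold and the transglutaminase gene TGM2 at 3.16-fold. Hypoxia and glycolysis genes were higher, 11 up and 2 down of 26, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00118, adjusted p = 0.514 with an estimated correlation).

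The earlier brain lists, again not independent evidence, went the same way as against the parental line. Both comparisons use the same 231BrM-2a arrays, so that agreement is partly built in. Of 14 reported high, 9 were lower and 2 higher in 231BrM-2a, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.407 with an estimated correlation). PTGS2 was 4.91-fold lower and HBEGF, a growth factor that binds the epidermal growth factor receptor, 3.94-fold (adjusted p = 0.000306 and 2.44e-05). Of 4 reported low, 3 were higher and 0 lower, as adjusted over the list alone (camera adjusted p = 0.00893, adjusted p = 0.407 with an estimated correlation). Unfolded protein and amino acid response genes were lower, 7 down and 0 up of 26, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.00118, adjusted p = 0.525 with an estimated correlation). PHGDH, which starts serine synthesis, was 4.38-fold lower. Immediate early genes (6 down, 0 up of 20, the same adjusted over the list alone), NF-kappaB targets (8 down, 5 up of 21, or 9 and 5 adjusted over the list alone) and lung metastasis genes (7 down, 3 up of 16, or 8 and 4 adjusted over the list alone) were called lower. Their camera adjusted p was 0.0198, 0.0226 and 0.0294, against an adjusted p of 0.54, 0.612 and 0.525 with an estimated correlation. All 3 calls were lost without 231BoM-1833 replicate 1 (camera adjusted p = 0.101, 0.316 and 0.0812), that of the immediate early genes also without 231BrM-2a replicate 1 (0.0552), and that of the NF-kappaB targets also with the dimmest 33.3% of clusters left out (0.0699). Fry called none of the immediate early genes (adjusted p = 0.0535), the NF-kappaB targets (0.0863) and the unfolded protein and amino acid response genes (0.0576).

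**Figure D3:**
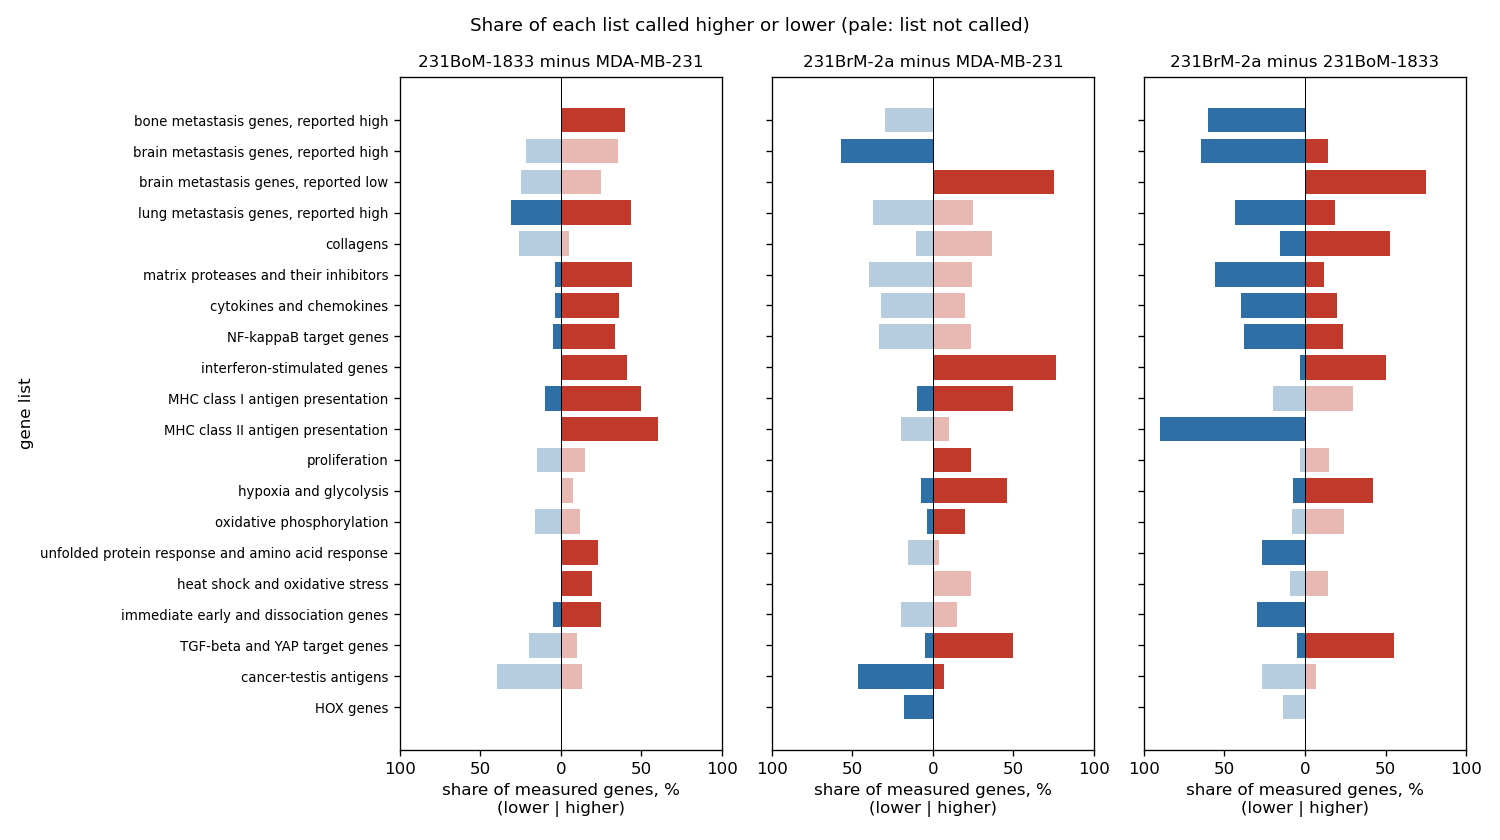
Share of the measured genes of 20 lists called higher (red, to the right) or lower (blue, to the left) in each of the 3 comparisons, in percent, with pale bars where camera did not call the list. Of the interferon-stimulated genes, 26 of 34 were higher in 231BrM-2a than in MDA-MB-231, and 9 of 10 class II genes were lower in 231BrM-2a than in 231BoM-1833.

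Limma called 4976 of 21214 clusters between the derivatives, 2642 higher and 2334 lower in 231BrM-2a, a majority that turned to 2209 higher and 2809 lower with arrays centred on their medians. Of the 4976 clusters, 972 differed at least 2-fold, 402 higher and 570 lower. Camera called 5 lists higher and 9 lower, against 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 16 with fry. The cluster count was 3079 without 231BrM-2a replicate 1 and 3001 without 231BrM-2a replicate 2, where the majority also turned (1475 higher, 1526 lower), as it did without 231BoM-1833 replicate 2 (2013 higher, 2090 lower).

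Some genes moved the same way in both derivatives against the parental line. MYO1D, the matrix protein gene MATN2 (6.66-fold in 231BoM-1833 and 8.41-fold in 231BrM-2a), TNFSF10 (4.52-fold and 6.63-fold), BST2 (3.59-fold and 3.49-fold) and the kinase gene DCLK1 (3.29-fold and 3.30-fold) were higher in both. TNFSF18 (13.5-fold and 10.3-fold), HSD17B2 (4.28-fold and 4.22-fold), ITGA10 (3.89-fold and 5.72-fold) and GABRA3, a neurotransmitter receptor subunit gene (2.72-fold and 3.89-fold), were lower in both. The fall of TNFSF18 in 231BrM-2a was 21.6-fold without 231BrM-2a replicate 1 and 4.88-fold without replicate 2. In all, 968 clusters were called in the same direction in both, 545 higher and 423 lower, where independent lists of those sizes would share 321 (187 and 134). In 100 simulations of unchanged derivatives against the same parental arrays, the mean was 0.1 and the highest 1. With nothing changed, hardly any cluster is called, so these simulations cannot show how many of the 968 come from the shared arrays. The parental line has only 2 arrays, too few to give each derivative 2 of its own, so part of the excess may come from the shared controls. Across clusters, the log2 changes of the derivatives correlated at r = 0.214, against 0.5 in the simulations, with a covariance of 0.0331 against 0.00845, a difference of 0.0247. An r of 0.5 follows from a shared control when nothing else differs, so it does not gauge the 0.214. The count of 968 was 386 without MDA-MB-231 replicate 1, 215 without MDA-MB-231 replicate 2, 503 without 231BrM-2a replicate 1, 468 without 231BrM-2a replicate 2, and 502 when clusters with no symbol were tested too.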

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

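The tests of explanations here were devised after the patterns were seen, and those of swapped labels, mixed cells, another line and leukocytes also after the values they rest on; only for the region beside the class II genes was the bound set before its value was computed.

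The derivatives changed in opposite directions against the parental line for 372 clusters, 250 higher in the bone line and lower in the brain line and 122 the reverse, where independent lists of those sizes would give 154 and 164. They include 13 genes named for the highest or lowest changes, for which the difference between the derivatives, brain minus bone, is given as a size only, since the opposite calls fix its sign. EHF differed by -6.10 ± 0.11, with 1.58 in the bone line and -4.52 in the brain line against MDA-MB-231. IL24 differed by -5.54 ± 0.26, IL13RA2 by -5.23 ± 0.14, MUC15 by -4.37 ± 0.11, ESM1, which encodes an endothelial proteoglycan, by -4.25 ± 0.15 and IL1B by -3.94 ± 0.21. In the other direction, TENM2 differed by 4.81 ± 0.14, SCNN1A by 3.40 ± 0.12, IL7R by 3.26 ± 0.20, MAOA by 3.09 ± 0.18, the receptor gene GPRC5B by 2.82 ± 0.24, ZBTB16 by 2.74 ± 0.16 and DAAM2, a Wnt pathway regulator gene, by 2.47 ± 0.15.

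Clusters with no gene symbol also differed. With all clusters tested together, 590 of 12083 were called between 231BoM-1833 and MDA-MB-231, 473 between 231BrM-2a and MDA-MB-231 and 827 between the derivatives, of which 150, 112 and 158 differed at least 2-fold.

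The arrays of 231BrM-2a went against both earlier brain lists, which raises the identity of the samples. A swap of the 2 derivative labels would need the bone list to stand higher in the arrays labelled 231BrM-2a. The median difference of its 9 genes without MMP1 was -0.605 (brain minus bone), with 5 lower and 0 higher, so this list argues against a swap. The brain lists, which raised the question, went as a swap would have them. Brain minus bone, 9 of 14 reported high were lower and 2 higher, and 3 of 4 reported low were higher and 0 lower. The lists conflict on this point. Other cells mixed in would have to make up at least 96.8% of the sample to lower MMP1 as seen, and 0 of 26 tracked leukocyte, red cell, platelet and endothelial markers rose, cells of which the sort for ESA would keep few, yet only 1 brain list gene fell by over 4-fold beyond 2 standard errors, too few to decide. The lowest correlation of a 231BrM-2a array with an MDA-MB-231 array was 0.9755 and the highest 0.9797, next to 0.9795 to 0.9832 for 231BoM-1833, but with no arrays of unrelated lines another line of origin cannot be told apart from a derivative that drifted. A real difference of the sorted subpopulation from the whole lines behind the earlier lists stays open and untested.

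Class II genes rose in 231BoM-1833 by a median of 1.51. Leukocytes would bring their own markers, but the median of 15 leukocyte genes was -0.0557 ± 0.032 (SE over genes), with 1 higher, CD14. This argues against leukocytes of many kinds, and the sort would keep few. Cells of 1 kind would move only some of these markers and could leave the median unchanged. More copies of the region would lift the neighbours too. The median of 50 genes beside the class II genes (mean log2 value above 7) was -0.0187 ± 0.054, with 7 higher and 5 lower. The medians of the 2 sides were -0.0681 and 0.173. This argues against a gain that spans both sides as the cause. A narrower gain stays open. Genes of the class I list were left out of the neighbours, and that list also rose, with 5 up and 1 down of 10. Only 1 gene outside both lists lay between the outermost class II genes (0.236). Regulation in the bone-selected line is an untested hypothesis, and CIITA at 0.054 ± 0.13 (adjusted p = 0.805) gave no sign of a higher activator transcript at this precision.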

How the results depend on the processing

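No named call and no list call changed direction under the alternatives run on it. Of the 440 named calls, each alternative's losses were counted: 173 at a change of at least 2-fold, 99 without MDA-MB-231 replicate 2, 75 without MDA-MB-231 replicate 1, 71 with all clusters tested, 68 and 57 without 231BrM-2a replicates 2 and 1, 37 and 26 without 231BoM-1833 replicates 2 and 1, 14 with only the 2 groups compared, 12 with the block and 8 or fewer in the others. Counts of called clusters left the range within 1.5 times of the value in the report in 3 kinds of setting. At a change of at least 2-fold they were 393, 625 and 972 for the comparisons bone line with parental, brain line with parental and brain line with bone line, and 70 for the overlap. With all clusters tested they were 2220 and 502 for the first and the overlap, counts that include unnamed clusters. Of the calls in the 3 comparisons, that setting kept 48.6%, 59.9% and 68.9%. With 1 array left out they ranged from 932 to 2936, from 1764 to 4751 and from 3001 to 4750. The overlap then ranged from 215 to 852. Each of these settings left out 1 array, so the number of arrays alone does not account for the ranges. For brain line with parental, the count rose to 4751 when either 231BoM-1833 array was left out, and fell when an array of the 2 lines compared was left out. With an estimated correlation, camera called 0 lists in each comparison. In the other settings run on the lists (fry, the block, quantile normalisation, the dimmest 33.3% left out, the trend and each array left out), 7, 6 and 10 of the 11, 10 and 14 called lists kept their call. Fry called 1, 6 and 5 lists that camera had not called, and the remaining settings together 4, 3 and 3. With arrays centred on their medians, the share of higher calls went from 53.3% to 60.8%, from 54.9% to 48.7% and from 53.1% to 44.0%, so the majority turned in the comparisons brain line with parental and brain line with bone line. No scaling alternative moved the median log2 change by over 0.1.

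The replicate numbers are given in the labels but do not pair the samples. Differences between replicates 1 and 2 correlated across lines at 0.036, -0.16 and -0.17. With the replicate number as a block, 2724, 3535 and 4564 clusters were called and 735 in the overlap, and with the numbers crossed, an alternative chosen after seeing the data, 3821, 4468, 5387 and 1144. With no level of background given, the signal over background that limits the dimmest clusters is unknown.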

Other observations

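The tests on neighbouring genes were devised after the correlations between lines had been seen, and that of an array effect as the whole cause also after those of the replicate differences; the bounds of the others were set before their values were computed.

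Groups that camera did not call still held genes that passed the test. Collagens had 7 up and 2 down of 19 in 231BrM-2a against MDA-MB-231, with the same counts adjusted over the list alone (camera adjusted p = 0.0631, adjusted p = 0.476 with an estimated correlation), while fry called them higher (adjusted p = 0.00626). COL4A1 rose 4.38-fold and COL4A2 3.06-fold, while COL6A3 fell 3.67-fold. Among 18 epithelial markers, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0863, adjusted p = 0.557 with an estimated correlation), while fry called them higher (adjusted p = 0.0481), with the keratin gene KRT7 up 2.51-fold and KRT19 down 3.03-fold. Among 18 mesenchymal markers, 5 rose and 3 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.676, adjusted p = 0.866 with an estimated correlation). The growth factor receptor gene PDGFRB rose 3.25-fold and the cadherin gene CDH11 fell 3.01-fold. Among 16 integrins, ITGB3 rose 4.67-fold and ITGA2 fell 2.61-fold. HAS2 fell in 231BrM-2a while CEMIP2, which encodes a protein tied to hyaluronan breakdown, rose 2.83-fold (adjusted p = 0.000219) and LAYN, a hyaluronan receptor gene, rose 2.01-fold (adjusted p = 0.000805).

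In the stem cell and pluripotency list, POU5F1, NANOG and BMI1 had no cluster with that symbol alone and were not tested. The other 17 genes were not called as a group in the sorted cells of either derivative. In 231BoM-1833, 3 of 17 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.607, adjusted p = 0.941 with an estimated correlation), and the integrin chain gene ITGA6 rose 1.74-fold (adjusted p = 0.00279). In 231BrM-2a, 1 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.458, adjusted p = 0.798 with an estimated correlation), and MYC fell 1.72-fold (adjusted p = 0.00104). KLF4 had differences of 0.086 ± 0.17 and 0.038 ± 0.17 in 231BoM-1833 and 231BrM-2a (adjusted p = 0.757 and 0.899).

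Genes that lie side by side changed together, over 10086 genes with a mean log2 value above 7. The rank correlation of log2 changes between adjacent genes was 0.252 in 231BoM-1833 and 0.332 in 231BrM-2a against MDA-MB-231, and 0.313 between the derivatives. Some stretches of 25 genes moved nearly as a block. From NUF2 to METTL13, 24 of 25 genes were higher in 231BoM-1833, with a median of 0.60, and from PBDC1 to ARMCX3, 24 of 25 were higher, with a median of 0.66. From CCDC127 to CCT5, 23 of 25 were lower there, with a median of -0.45. In 231BrM-2a, 25 of 25 genes from GTPBP6 to TXLNG were higher, with a median of 0.59, 24 of 25 from MINDY2 to PCLAF were higher, with a median of 0.66, and 23 of 25 from FECH to CNDP2 were lower, with a median of -0.66. The stretch from BLTP3A to ZFAND3, near the class II genes, had a median of 0.38 in the bone line and -0.51 in the brain line. These stretches were picked after their values were seen.

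Chance order is argued against, since 1000 random orders gave at most 0.035. Shared probes or related genes side by side are argued against as well, since genes 5 places apart with different symbol stems still correlated at 0.213 or more. An array effect that follows gene order may have a part, or real differences between the replicate samples, which these data cannot tell apart: differences between replicates correlated between neighbours at up to 0.134, in 231BoM-1833, against 0.0464 in MDA-MB-231 and 0.0418 in 231BrM-2a. As the whole cause, an effect that varies between replicates is argued against, since such differences carry at most 6.34% of a comparison's neighbour covariance. Copy number differences between the lines are a hypothesis that these data hold no DNA to test, and a batch that follows the lines could not be excluded, as the labels give none.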
